A study of Arabidopsis thaliana with 24 samples.

How the data were processed

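Arabidopsis seedlings were treated and total RNA was isolated from leaves, per the labels' protocols. The RNA was labelled with a single dye (Alexa555) and hybridised to a spotted array. Each spot also carried a DNA stretch that binds a Cy5-labelled oligonucleotide, with which spots of poor quality were found and removed, per the labels. The deposited values of the authors were on a log scale, taken as log2 because they range from 0.450 to 11.4. The base of the log, the scanner, the background correction and the normalization between arrays are not given in the sources used here. A natural log is not excluded by the values, and p-values do not depend on the base. Array medians differed, so arrays were not brought to a common median, and many values recurred exactly within an array (from 311 to 405 distinct values per array), for which no cause is given.

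The 24 arrays fell into 8 groups of 3 by genotype, treatment and time, from the labels, and carried set numbers 1 to 3. Nothing says that the sets came from separate experiments, so p-values measure only the spread between these samples, which may be technical. No array duplicated another. The table held 0 missing values. The probe table gave 1 gene for 181 probes and several for 0, and 395 probes are unnamed here. Of these genes 180 were matched by gene identifier to RefSeq names of assembly TAIR10.1, and 1 kept its older name. No coordinates are printed because the sources name no build for the probes.

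All comparisons used limma 3.58.1 in R 4.3.3 with 1 model of 8 group means over all 24 arrays, empirical Bayes moderation (prior degrees of freedom 5.39) and Benjamini-Hochberg adjustment within each comparison over all probes, with a threshold of 0.05. No probe was filtered. The comparisons were the 4 flg22 responses, 4 genotype differences, their interaction at each time, the genotype difference over all conditions, the change of the response between the times in each genotype, and the time change in mock. Total least squares slopes compared the responses across genes without a test. Gene groups were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Of 16 lists fixed before the data were examined, 2 had at least 3 measured genes, so 10 more were chosen after the names of the probes were known but before genes were compared between groups. Genes were named by a rule fixed beforehand: the 10 that rose most and the 8 that fell most in each response among those past the threshold with the same direction in all sets, up to 20 past the threshold for other comparisons (or the 5 smallest p where fewer than 5 passed), and examples of each list. The rule was applied to probes with a gene name.

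Set numbers were checked for pairing by correlating the deviations of arrays from their group means. Same-numbered arrays of different groups had a median correlation of 0.336 (from -0.09 to 0.714), and differently numbered arrays -0.16. The second value largely follows from the first, since deviations cancel within each group, and adds no separate evidence. In 7 of the 8 comparisons of 2 groups every same-numbered pair was over 0.1, so there the numbers pair the samples. The exception was the genotype comparison with flg22 at 3 h (lowest -0.01). The main fit did not use this pairing, so its standard errors, p-values and intervals include the spread between sets. The set number entered only as a replicate block, among the alternatives below.

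The fit was tested on simulated data made from the observed means and spreads, with 100 probes changed in each of 20 simulations. Noise was drawn independently for each probe and array, without the correlation within sets described above. For a genotype difference in mock at 30 min, 90.9% of changes of 1 log2 unit and 47.9% of changes of 0.5 were recovered. For the genotype difference over all conditions 90.6% of changes of 0.5 were recovered, and for the interaction at 30 min 68.6% of changes of 1. With fewer changed probes the adjustment is stricter, so these rates may overstate the recovery of a few changed genes. The alternatives were median centring, quantile normalization, leaving out the dimmest probes (432 kept), a trended and robust prior, the set number as a fixed or random replicate block, only the compared arrays in the fit, and leaving out each array or set. Centring on the 19 housekeeping genes was added after the numbers of probes past the threshold under other scalings had been seen.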

Results

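The series measured transcript levels in Arabidopsis thaliana on 24 spotted arrays. Seedlings of the wild-type accession Col and of mpk11, a T-DNA insertion line in the gene of the MAP kinase MPK11, received 1 µM flg22 or water (mock). The peptide flg22 is a stretch of bacterial flagellin that plants perceive as a sign of infection. RNA of their leaves was taken after 30 min or 3 h, which gives 8 groups of 3 arrays, numbered as sets 1 to 3. The probe table listed a gene for 181 probes, and 395 more are unnamed here. MPK11 and the other members of the fixed MAP kinase list were not among the named probes, so the transcript of the mutated gene was not analysed here and could not check the genotype labels. All changes are differences of deposited log values, taken as log2 although the base of the log is not stated. The number of arrays limits the precision. Array medians lay between 3.34 and 3.76 in mock and between 4.02 and 4.17 with flg22.

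In wild-type seedlings at 30 min, genes of transcription factors and calcium-binding proteins were among those that rose with flg22. STZ (AT1G27730, also ZAT10), a zinc-finger transcription factor, went from 2.53 ± 0.13 in mock to 7.26 ± 0.40 with flg22 (log2, SD, n = 3), a rise of 4.73 (SE 0.21; limma adjusted p = 1.49e-14). AT4G27280, an EF-hand calcium-binding protein, rose by 4.64 (SE 0.21), and the transcription factors WRKY53 (AT4G23810) and WRKY22 (AT4G01250) rose by 3.74 (SE 0.16) and 3.25 (SE 0.19). AT4G39670 rose by 3.73, AT5G52760 by 3.43, AT2G36690 by 2.74 and AT3G54150 by 2.69. The calmodulin-like gene CML42 (AT4G20780) and EXO (AT4G08950) each rose by 2.40. Each of these 10 genes was higher in all 3 sets, which the rule that named them required. Of the 10 probes with the largest rise, 6 are unnamed here.

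By gene group at 30 min in wild type, all 4 measured WRKY genes rose, WRKY29 by 0.78 and WRKY6 by 1.15 beside the 2 above. The group stood above the other probes (median 2.20, camera adjusted p = 5.33e-04, and adjusted p = 0.00937 with an estimated correlation). The 3 measured early flagellin-response markers were WRKY22, WRKY29 and WRKY53, so they do not stand apart from the WRKY group, and all rose (camera adjusted p = 5.88e-04, and adjusted p = 0.00937 with an estimated correlation). Adjusted over the list alone, 4 WRKY genes and 3 early markers passed, here and in the 3 other responses. All 5 calcium sensors rose, among them AT5G39670 by 1.95 and AT2G41410 by 1.39 (camera adjusted p = 5.33e-04, and adjusted p = 0.0202 with an estimated correlation). Of the 6 chitinase, defensin and proteinase inhibitor genes 3 rose, the chitinase genes AT4G01700 by 1.65 and AT2G43620 by 1.48 and the proteinase inhibitor gene AT2G38870 by 0.89, with a camera adjusted p of 0.209 for the group. GRX480, a glutaredoxin of salicylic acid signalling, rose by 0.72, while the ethylene and jasmonate marker PDF1.2 (AT5G44420) differed by 0.72 without passing (limma adjusted p = 0.269). EF1A (AT5G60390), the single measured reference gene, differed by -0.57 (limma adjusted p = 0.0591). None of the 19 housekeeping genes passed at this time, though 10 fell after median centring and 9 after quantile normalization, and none of the 7 UDP-glycosyltransferase, 5 chaperone and 3 histone H3 genes passed (camera adjusted p = 0.229, 0.229, 0.424 and 0.458).

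In total 117 probes were higher and 1 lower with flg22 at 30 min in wild type (limma, adjusted p below 0.05), of which 84 were higher by at least 1 log2 unit. This split depends on how the arrays are scaled. Centring each array on its median moved all changes by -0.47 and gave 87 higher and 253 lower, and quantile normalization gave 92 and 157. The median change of all probes was 0.056 in the deposited scaling and -0.42 after median centring. Centring on the housekeeping genes, an alternative added later, gave 114 higher and 3 lower. With the set number as a replicate block, 127 were higher and 5 lower.

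At 3 h in wild type, 2 chitinase genes and a proteinase inhibitor gene were among those that rose most. AT2G43620, a chitinase family gene, went from 3.61 ± 0.50 to 8.96 ± 0.09 (log2, SD, n = 3), a rise of 5.35 (SE 0.20; limma adjusted p = 1.27e-15). The proteinase inhibitor gene AT2G38870 rose by 4.80 (SE 0.18), the chitinase gene AT4G01700 by 4.45 (SE 0.15), the FAD-linked oxidoreductase gene AT1G26380 by 4.30 (SE 0.18) and the peroxidase gene AT5G64120 by 4.28 (SE 0.20). AT2G04400, indole-3-glycerol phosphate synthase of the tryptophan pathway, rose by 2.88, AT2G36690 by 3.27, AT2G42360 by 2.74, WRKY29 by 2.49 and AT3G54150 by 2.40. Falling genes moved less: AT3G16370, a GDSL-type lipase family gene, fell by 1.41 (SE 0.18), AT3G18050 fell by 1.01, the peroxidase gene AT2G37130 fell by 0.85 and RAP (AT2G31890) fell by 0.71. TUB6, a beta-tubulin, fell by 0.70, the histone H3 gene AT1G09200 fell by 0.68, AT3G12390 fell by 0.67 and CDI (AT1G64980) fell by 0.57. The call of TUB6 was lost without flg22 array 2 or 3 or mock array 2 (limma adjusted p from 0.0660 to 0.172), that of AT3G12390 without flg22 array 2 or 3 or mock array 1 or 2 (limma adjusted p from 0.0571 to 0.0905), and those of AT2G37130 and AT1G09200 without set 3 (limma adjusted p = 0.108 and 0.0755).

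By group at 3 h in wild type, 4 of 6 chitinase, defensin and proteinase inhibitor genes rose (median 2.54, camera adjusted p = 0.0275). The call of this group was lost with an estimated correlation (adjusted p = 0.0536) and with the replicate block (camera adjusted p = 0.0522). All 4 WRKY genes and all 3 early markers were again higher (camera adjusted p = 0.00702 and 0.00702; with an estimated correlation adjusted p = 0.0303 and 0.0303). Of the chaperone genes 3 of 5 rose, BIP1 of the endoplasmic reticulum by 1.85 and the HSP70 gene AT3G09440 by 1.48 (camera adjusted p = 0.145). HSP70 and histone H3 genes belong to near-identical families, so the identity of the transcripts these probes report is uncertain. Of 7 UDP-glycosyltransferase genes 3 rose, UGT74B1 of glucosinolate synthesis, IAGLU by 1.11 and UGT76B1 by 1.05, while the median of the group, 0.31, turned to -0.22 after median centring (camera adjusted p = 0.465). Of 3 histone H3 genes 1 fell, AT1G09200 (camera adjusted p = 0.117). Of 3 peroxidase genes 1 rose, AT5G64120, and 1 fell, AT2G37130, while AT5G19890 differed by 0.81 without passing (camera adjusted p = 0.725 for the group). Among 19 housekeeping genes 2 rose and 2 fell (median -0.03, camera adjusted p = 0.067), while 14 fell and 0 rose after median centring (camera adjusted p = 0.0480).

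At 3 h in wild type 184 probes were higher and 37 lower, 121 and 12 of them by at least 1 log2 unit. Of the 117 probes higher at 30 min, 88 were also higher at 3 h, where 37.4 would overlap by chance. Median centring moved the changes by -0.53 and gave 123 higher and 256 lower, and quantile normalization gave 130 and 184. Centring on the housekeeping genes gave 198 higher and 32 lower.

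The flg22 response was measured in mpk11 in the same way. At 30 min AT4G27280 rose by 5.21 (SE 0.21; limma adjusted p = 3.63e-15), STZ by 4.87, AT5G52760 by 4.05, WRKY22 by 3.57, WRKY53 by 3.51, AT4G39670 by 2.96 and CML42 by 2.73. AT2G36690 rose by 2.65, AT3G54150 by 2.50 and AT1G26380 by 2.18. AT3G16370 fell by 0.59, AT1G62660, a vacuolar invertase gene, fell by 0.45 and IAGLU (AT4G15550) fell by 0.41. All 3 calls were lost with only the 2 groups compared in the fit. The call of AT3G16370 was lost without mock array 1 (limma adjusted p = 0.147), that of AT1G62660 without any flg22 array or mock array 1 or 2 (limma adjusted p from 0.0544 to 0.205) and that of IAGLU without array 2 or 3 of either treatment (limma adjusted p from 0.0810 to 0.160). All 4 WRKY genes, all 3 early markers and all 5 calcium sensors rose here too (camera adjusted p = 0.00109, 8.95e-04 and 3.52e-04). With an estimated correlation these were adjusted p = 0.0113, 0.0113 and 0.0169. In all, 118 probes were higher and 9 lower (14 lower with the replicate block), and of the probes higher in wild type 110 were also higher in mpk11, where 24.0 would overlap by chance. Median centring gave 87 higher and 266 lower, quantile normalization 97 and 170, and centring on the housekeeping genes 110 and 10.

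At 3 h in mpk11 AT2G43620 rose by 6.07 (SE 0.20; limma adjusted p = 1.88e-16), AT2G38870 by 5.11, AT1G26380 by 4.77, AT5G64120 by 4.72 and AT4G01700 by 4.54. AT2G36690 went from 2.92 ± 0.20 to 6.42 ± 0.34 (log2, SD, n = 3). AT2G04400 rose by 2.96, AT3G54150 by 2.75, AT2G42360 by 2.71 and WRKY29 by 2.64. AT3G16370 fell by 1.38, AT3G18050 fell by 1.16, RAP fell by 0.81, AT2G37130 fell by 0.79 and AT1G09200 fell by 0.64. TUB6 fell by 0.62, the dehydrin gene COR47 fell by 0.57 and AT-HF of histidine synthesis fell by 0.50. Single arrays ended the calls of TUB6 (any but flg22 array 1; limma adjusted p from 0.0503 to 0.163), COR47 (flg22 array 1 or 3 or mock array 2; limma adjusted p from 0.0984 to 0.224), AT-HF (flg22 array 1 or 2 or mock array 1 or 3; limma adjusted p from 0.0628 to 0.262) and AT1G09200 (mock array 1; limma adjusted p = 0.0593). COR47 and AT-HF also did not pass with only the 2 groups compared in the fit. Of 6 chitinase, defensin and proteinase inhibitor genes 4 rose (camera adjusted p = 0.0188, and adjusted p = 0.0412 with an estimated correlation). In all, 198 probes were higher and 37 lower (56 lower with the replicate block), and 173 of those higher in wild type were also higher in mpk11, where 63.2 would overlap by chance. Median centring gave 122 higher and 281 lower, quantile normalization 126 and 194, and centring on the housekeeping genes 198 and 34.

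**Figure D1:**
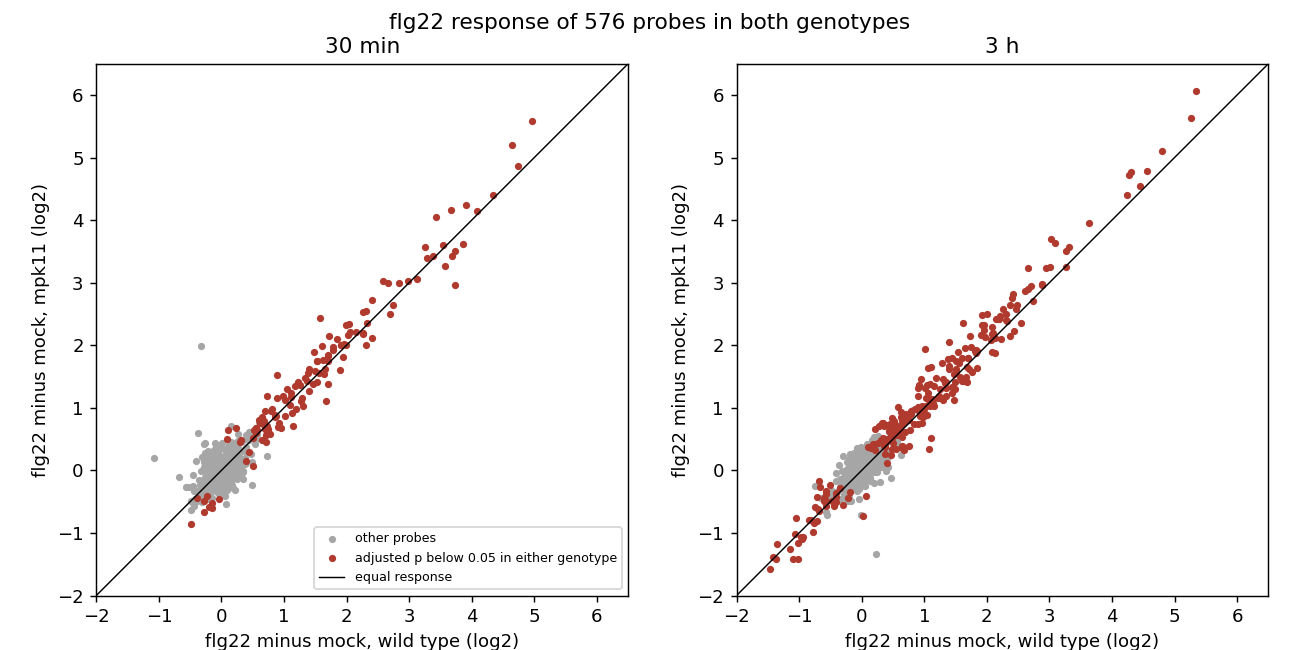
Change with flg22 in wild type (horizontal axis, log2) against mpk11 (vertical axis, log2) for all probes at 30 min and 3 h, each point the difference of means of 3 arrays per group, with the line of equal response. Points follow the line at both times, with slopes of 1.04 and 1.07.

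Compared directly, no gene passed the test between mpk11 and wild type in any condition. With flg22 at 30 min, AT4G39670 differed by -0.69 (95% interval -1.09 to -0.29; limma adjusted p = 0.267), AT4G33540 by -0.47, AT2G28400 by -0.50, IAGLU by -0.35 and AT1G62660 by -0.38, none passing. PDF1.2, named here after its values were seen, differed by -0.91 and passed with array 3 of the flg22-treated wild type at 30 min left out (limma, a difference of -1.59, adjusted p = 0.00396). With flg22 at 3 h the smallest p-values belonged to AT4G25900 (0.39), AT2G32150 (-0.39), AT3G48070 (-0.27), AT4G24340 (-0.26) and AT5G20030 (-0.20). In mock at 30 min the HSP70 gene AT3G09440 differed by -0.64 (limma adjusted p = 0.471), AT4G17470 by -0.36, the splicing factor gene ATU2AF65A by 0.50, AT2G38870 by -0.49 and AT3G12390 by 0.60. In mock at 3 h AT2G43620 differed by -0.52, AT-HF by 0.36, AT2G36690 by -0.30, AT1G76960 by -0.36 and BGLU45 by -0.27. Among the gene groups, the chaperones lay lower than the other probes in mock at 30 min (camera adjusted p = 0.0475, and adjusted p = 0.434 with an estimated correlation). The housekeeping genes lay higher than the other probes with flg22 at 30 min (camera adjusted p = 0.0374, and adjusted p = 0.0647 with an estimated correlation). Both groups had 0 members past the threshold. In limma 0 probes passed in each of the 4 comparisons, while 50 and 6 in mock and 24 and 8 with flg22, at 30 min and 3 h, had an unadjusted p under 0.05, where 28.8 are expected by chance. The fit behind these p-values kept the spread between sets in its error, which can make p-values of paired samples too large. Counts under 28.8 are therefore no sign that the genotypes are alike. The median half-width of the 95% intervals, from the same fit, was 0.377 log2 units.

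The responses themselves were compared by the interaction of genotype and flg22. At 30 min AT4G39670 had a difference of -0.77 between the responses, mpk11 less wild type (95% interval -1.33 to -0.21; limma unadjusted p = 0.00964, not passing after adjustment), and AT2G38870 (0.63), AT2G28400 (-0.56), ARA6 (0.54) and AT1G64710 (0.46) came next. At 3 h AT2G43620 (0.72), AT3G48070 (-0.48), AT2G32150 (-0.59), AT4G39830 (0.41) and AT1G26380 (0.47) had the smallest p-values, none passing. In limma 0 probes passed at either time, with 7 at 30 min and 8 at 3 h under an unadjusted p of 0.05. These low counts carry the same limit, since the fit kept the spread between sets in its error. Across the probes, which are not independent replicates, the slope of the mpk11 response on the wild-type response was 1.04 at 30 min (SD over sets 0.0261, n = 3) and 1.07 at 3 h (SD over sets 0.0632, n = 3). Across genes the Pearson correlations were 0.960 at 30 min and 0.978 at 3 h, and Spearman's rho was 0.690 and 0.923.

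Over all 4 conditions together, AT4G17470 differed by -0.19, AT3G09440 by -0.29, AT4G33540 by -0.24, PDF1.2 by -0.55 and the small heat shock protein gene AT2G29500 by -0.34 in mpk11, none passing (limma adjusted p from 0.232 to 0.347). The 5 chaperone genes lay lower as a group (median -0.23, camera adjusted p = 0.0428), a call lost with an estimated correlation (adjusted p = 0.479) and after centring on the housekeeping genes (camera adjusted p = 0.0652). The 19 housekeeping genes lay higher than the other probes as a group (median 0.01 against -0.03 for all probes, camera adjusted p = 0.0428). A median near 0 shows no clear rise in mpk11 itself. This call was also lost with an estimated correlation (adjusted p = 0.119). In limma 0 probes passed, and 49 had an unadjusted p under 0.05, of which 43 were lower in mpk11. With the set number as a random replicate block, the unnamed probes 290 (-0.42) and 450 (-0.33) passed (limma adjusted p = 0.0465 for each). PDF1.2 passed with array 3 of the flg22-treated wild type at 30 min left out (limma, a difference of -0.72, adjusted p = 0.00524).

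The flg22 response of single genes differed between 30 min and 3 h. In wild type it was larger at 3 h for AT2G38870 by 3.91 (SE 0.26; limma adjusted p = 1.60e-10), AT2G43620 by 3.87, AT4G01700 by 2.80, AT2G04400 by 2.78 and AT5G64120 by 2.67. The response of AT4G27280 fell by 3.57 between the times (SE 0.29; limma adjusted p = 3.94e-09), that of STZ fell by 2.54, that of AT5G52760 fell by 2.37, that of EXO fell by 2.35 and that of WRKY53 fell by 1.52. The WRKY genes went both ways, since the response of WRKY29 was larger at 3 h by 1.71. The group of chitinase, defensin and proteinase inhibitor genes moved up (3 of 6 members, camera adjusted p = 0.0173 in wild type and 0.011 in mpk11; with an estimated correlation adjusted p = 0.0566 and 0.0427, which ends the call in wild type). CDI rose by 1.09 at 30 min and fell at 3 h in wild type, a difference of -1.67. The calls of AT5G39670 in wild type and AT4G38540 in mpk11 were lost without set 3 (limma adjusted p = 0.0544 and 0.0529), where 93 probes passed in wild type and 105 in mpk11. In wild type the response was larger at 3 h for 93 probes and smaller for 66 (80 and 86 after quantile normalization), and in mpk11 for 90 and 70. Of these, 75 and 58 were shared by both genotypes, where 14.5 and 8.02 would be by chance.

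**Figure D2:**
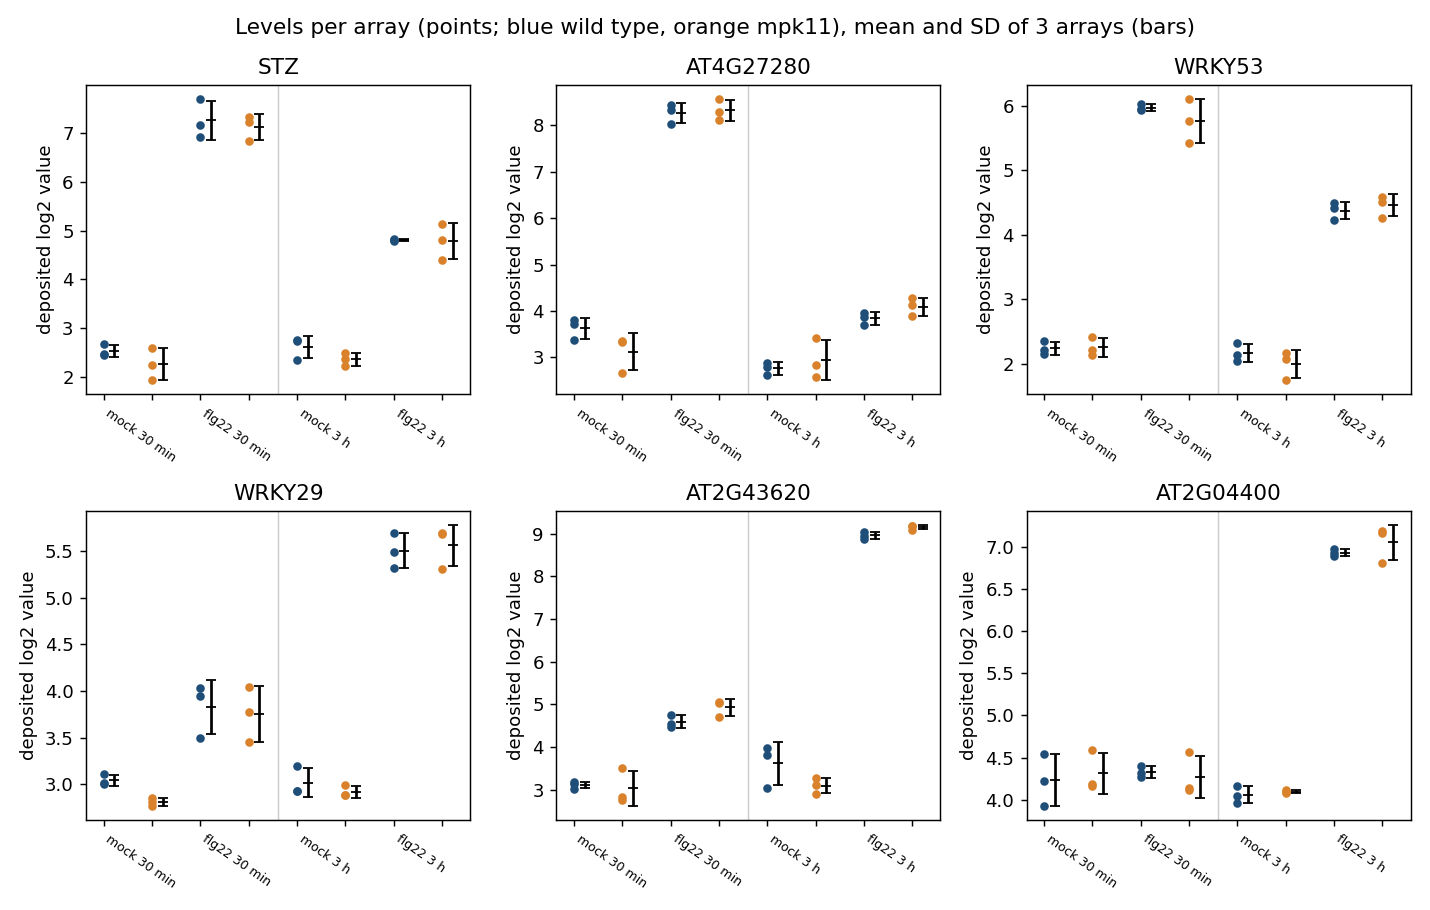
Deposited log2 values of 6 genes on each array (points, blue for wild type and orange for mpk11) by treatment and time, with the mean and SD of 3 arrays as bars. STZ, AT4G27280 and WRKY53 stand highest with flg22 at 30 min, while WRKY29, AT2G43620 and AT2G04400 stand highest with flg22 at 3 h.

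Mock-treated seedlings also changed between 30 min and 3 h. Over both genotypes AT3G28270 fell by 2.02 (SE 0.20; limma adjusted p = 1.24e-07), AT3G57020 fell by 1.23, the calmodulin-like gene AT2G41090 fell by 1.16 and EXO fell by 0.89, while CCL (AT3G26740) rose by 1.57 and the peroxidase genes AT2G37130 and AT5G19890 rose by 0.81 and 0.80. All 5 chaperone genes fell, AT3G09440 fell by 0.98, AT5G48570 fell by 0.72, AT2G29500 fell by 0.68, BIP1 fell by 0.61 and Hsp70-2 fell by 0.56 (camera adjusted p = 0.0074), a group call lost with an estimated correlation (adjusted p = 0.255). The call of the 3 peroxidase genes was lost the same way (camera adjusted p = 0.0087, and adjusted p = 0.0626 with an estimated correlation). Each flg22 response is flg22 less mock of the same time. Mock changes such as those of AT3G09440, BIP1 and AT2G37130 therefore enter the change of their responses between the times. AT1G76960 fell by 0.79, GSTF3 fell by 0.73, AT2G26690 fell by 0.73, the glucosinolate transporter gene GTR1 fell by 0.68, the sulfite reductase gene SIR fell by 0.58, SDH1-1 fell by 0.55 and LHCB4.3 fell by 0.54, while AT2G37190 rose by 0.54. In all, 23 probes were higher and 95 lower at 3 h, and median centring gave 40 and 57 and quantile normalization 47 and 71. Single arrays of the 12 ended the calls of AT5G19890 and AT2G37190 (9 arrays each; limma adjusted p up to 0.136 and 0.145), SIR (7 arrays; limma adjusted p up to 0.157), Hsp70-2 (4 arrays; limma adjusted p up to 0.0780) and GSTF3 (array 1 of either genotype at 30 min; limma adjusted p = 0.0538 and 0.0538). Median centring ended the calls of SIR, Hsp70-2 and LHCB4.3 (limma adjusted p = 0.143, 0.130 and 0.0615). Without set 3, 58 probes passed and AT2G26690, AT5G48570 and AT2G29500 did not (limma adjusted p = 0.113, 0.101 and 0.131), and without set 1 BIP1 and SDH1-1 did not (limma adjusted p = 0.134 and 0.0716).

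**Figure D3:**
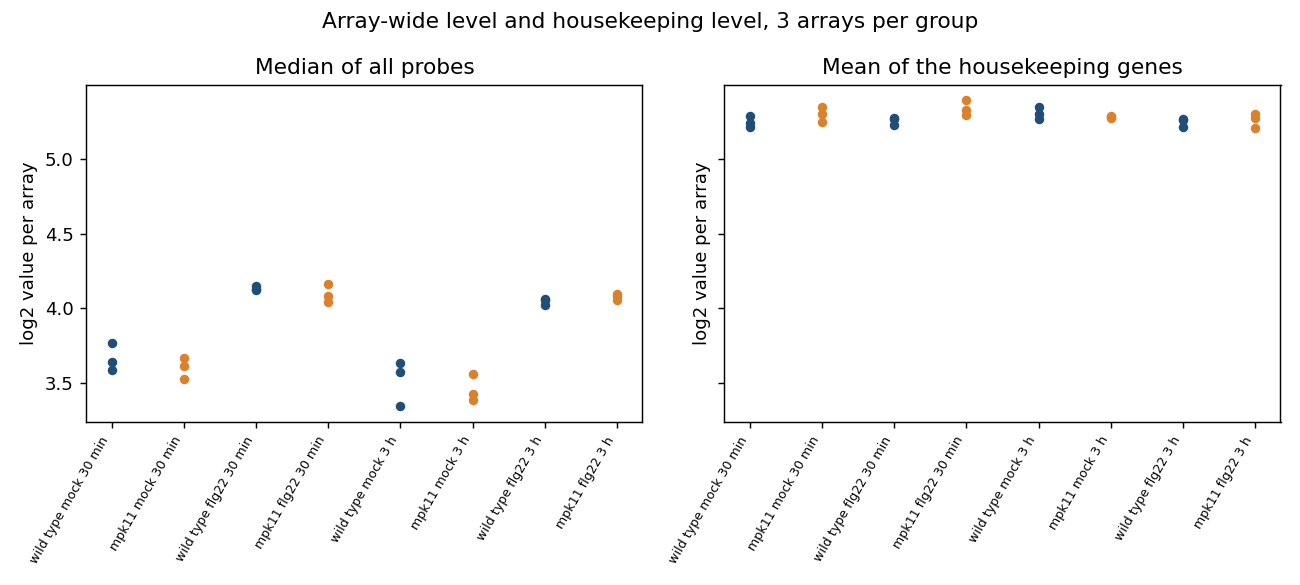
Median log2 value of all probes per array (left) and mean log2 value of 19 housekeeping genes per array (right), 3 arrays per group (blue wild type, orange mpk11). All flg22 arrays stand at 4.02 or above and all mock arrays at 3.76 or below in the left panel, while the groups overlap in the right panel.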

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

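The sorting of the splits by which arrays they exchange was chosen after the result was seen. By the test of the difference itself, the flg22 response at 3 h differed from that at 30 min for 159 probes in wild type and 160 in mpk11. Among the named genes the difference in wild type (log2, response at 3 h less response at 30 min) was AT2G38870 (3.91), AT2G43620 (3.87), AT4G27280 (-3.57), AT4G01700 (2.80), AT2G04400 (2.78), AT5G64120 (2.67), STZ (-2.54), AT5G52760 (-2.37), EXO (-2.35), AT4G39670 (-2.33), AT1G26380 (2.04), AT5G60800 (-1.94), AT4G26400 (-1.92), BIP1 (1.92), WRKY29 (1.71), CDI (-1.67), UGT74B1 (1.66), AT5G39670 (-1.61), AT3G09440 (1.60) and WRKY53 (-1.52). In mpk11 it was AT2G43620 (4.17), AT4G27280 (-4.06), AT2G38870 (3.58), AT2G04400 (3.00), AT4G01700 (2.92), AT5G52760 (-2.81), AT5G64120 (2.73), AT1G26380 (2.60), STZ (-2.45), AT5G60800 (-2.18), EXO (-2.10), UGT74B1 (1.95), AT4G26400 (-1.84), WRKY29 (1.70), AT5G39670 (-1.68), AT3G13950 (1.63), IAGLU (1.55), BIP1 (1.53), AT4G38540 (1.51) and CDI (-1.41).

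Splits of the arrays that mixed the times within each treatment were drawn to see how often chance gives as many probes. In wild type 6 of 100 splits, the real one included, called at least 159 probes (highest other 185), and in mpk11 9 of 100 called at least 160 (highest other 230), so chance is not excluded at a share of 0.05 by this count. The median of the other splits was 0 in both genotypes. Of the 5 other such splits in wild type 3 were within 1 exchange of arrays of the real split, and 2 exchanged the times in a single treatment or were within 1 exchange of this. Of the 8 in mpk11 2 were of the first kind and 6 of the second, which tests the sum of the time effects rather than their difference. The splits that reached the real counts thus kept most of the time structure of the arrays.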

How the results depend on the processing

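All alternatives but centring on the housekeeping genes, added after the data were seen, were planned. No named gene past the threshold changed direction under any of them. Counted over all probes in the 4 responses under the 3 scalings and the fixed block, 1 probe passed in the other direction, in mpk11 at 3 h under quantile normalization. Median centring and quantile normalization moved the number of probes past the threshold by over 1.5 times in the responses: in wild type at 30 min to 340 and 249, at 3 h to 379 (median centring), in mpk11 at 30 min to 353 and 267 and at 3 h to 403 (median centring). The alternatives' own construction shows the cause, since they shift all changes by -0.47 to -0.62 under median centring. The median change of all probes was 0.056 to 0.20 in the deposited scaling and -0.39 to -0.43 after median centring. Centring on the housekeeping genes gave 117, 230, 120 and 232. With the set number as a fixed replicate block the 4 responses called 132, 257, 149 and 276 probes, the 3 time comparisons 184, 213 and 149, and the genotype comparisons and interactions 0. Beyond the values given with the results it changed no other call of a named gene. As a random replicate block it called 2 probes lower in mpk11 over all conditions, both unnamed here; the cause was not tested. By set number 23 of 24 arrays correlated best with their own set, a hint from the data. In the comparisons without pairing by number, the block made the calcium sensor and chaperone groups pass in the time comparison in wild type (camera adjusted p = 0.0463 and 0.0453).

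With arrays or sets left out, the responses called 103 to 116, 172 to 216, 97 to 133 and 190 to 225 probes in wild type at 30 min and 3 h and in mpk11 at 30 min and 3 h. The genotype comparison with flg22 at 30 min and the one over all conditions called 0 to 1, and the other genotype comparisons and interactions 0. The change between the times called 93 to 161 in wild type and 105 to 177 in mpk11 and the mock comparison 58 to 120, each lowest without set 3, with fewer arrays. The slopes ranged from 1.01 (without array 3 of wild-type mock) to 1.07 (without set 2) at 30 min and from 1.05 to 1.10 at 3 h. Of 119 named gene values past the threshold, 95 passed under every alternative. Of the 119, 14 were lost with a single array left out, 6 under a scaling and 0 under a block. In the responses these genes were named for large changes with the same direction in all sets, so they do not represent all calls. Over all probes, median centring kept 88 of 118 calls in the same direction in wild type at 30 min and 160 of 221 at 3 h. In mpk11 it kept 96 of 127 at 30 min and 159 of 235 at 3 h. Quantile normalization kept 93, 167, 106 and 163, and centring on the housekeeping genes 114, 216, 119 and 229, in the same order. Centring on the fixed reference genes was not run because 1 of them was measured, and alternatives for missing values and linear values did not apply. The signal over background of the arrays is unknown here.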

Other observations

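The aspartyl protease-like gene AT3G51330 rose by 1.08 in wild type and 1.03 in mpk11, and AT1G03220 by 1.44 and 1.80, so that 2 of the 4 genes of this group rose at 3 h in each genotype. The receptor-like kinase gene AT3G09010 rose by 0.85 and 0.97, while AT1G11050 rose at 30 min by 1.27 and 1.11 and differed at 3 h by 0.13 and 0.37 without passing. In the group of 6 glucosinolate and sulphur genes, GTR1 rose at 30 min by 0.93 in wild type and 0.76 in mpk11, while UGT74B1 and AT2G04400 rose at 3 h (camera adjusted p = 0.465 for the group in wild type). Of 4 kinase genes 2 rose at 3 h in wild type and 1 in mpk11, and of the 6 glucosinolate and sulphur genes 2 rose in each. The camera adjusted p of the aspartyl protease-like group was 0.725 and of the kinase group 0.732 in wild type at 3 h. In wild type at 3 h median centring turned the medians of the kinase and glucosinolate groups from above to below 0, as quantile normalization did for the glucosinolate group, and at 30 min both turned the median of the aspartyl protease-like group.

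The test of a factor as large as the shift of the array medians and the comparisons of splits by set were chosen after the results were seen, and the other tests with the counts and array medians known. The excess of rises over falls with flg22 may come from the scaling of the arrays. A factor that raised every probe by the shift of the array medians (0.47 to 0.62 log2 units) would raise the housekeeping genes as much. Their median change was at most 0.0844 of that shift, and at most 0.258 with its SD over sets added. The bound of 0.5 was set with these values known, so being under it decides nothing. The median change of all probes was also under that shift, from 0.0558 to 0.202 (SD over sets at most 0.0491). Neither the 19 housekeeping genes nor the median probe shared the shift in the deposited scaling. This argues against a factor of that size, unless true falls of most probes offset it. A common factor as small as the median change of all probes cannot be told apart. The mean housekeeping median of the 4 responses over their mean all-probe median was -0.0182. In wild type at 30 min, however, this ratio was 0.714, and the bound set beforehand was not met. Whether the authors' scaling was anchored on such genes, which lay 0.119 below the all-probe median change, cannot be told apart from a real rise without a measure independent of the scaling. Lifting of dim probes by background is argued against, since the brightest 192 probes had a higher median change than the dimmest 192 in each response. In wild type at 30 min and 3 h these medians were 0.10 and 0.20 against -0.0025 and 0.05. In mpk11 they were 0.11 and 0.18 against 0.05 and 0.12. Taken as means of the 4 responses, their ratio was 2.78. At 3 h the middle 192 probes rose most (0.32 in wild type and 0.37 in mpk11). A rise of genes chosen for the array stays open and untested.

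The absence of called genes between the genotypes may reflect the number of arrays. On average 3.95% of probes had a 95% interval that reached a difference of 1 log2 unit, and 6.42% did in mock at 30 min, above the bound of 5%, so larger differences are not excluded for all probes. For a difference of 0.5 log2 units the share was 53.6%, so changes of that size in a single condition may be hidden. These intervals come from the main fit, which did not use the pairing of the samples by set number. For the mean difference over all 4 conditions the limit was tighter, with 0 probes reaching 1 and 5.21% reaching 0.5, and for the interactions at 30 min and 3 h it was wider, with 14.2% at both times reaching 1 and 88.9% and 86.3% reaching 0.5. An effect of the mutation too small for these arrays stays open.

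The 50 probes with an unadjusted p under 0.05 in mock at 30 min may rest on 1 array. Without array 1 of mpk11 in mock the number was 23, and without array 2 of mpk11 it was 92. Another split of the 6 arrays gave 114 such probes, and 10 splits are too few for a share under 0.05, so chance cannot be told apart from a genotype effect. That split parts 1 of the 3 set pairs, and the 6 such splits gave 44 to 114. The 3 others that part all 3 pairs, as the real one does, gave 13, 39 and 17.

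Other splits of the arrays were counted for every comparison. For the 4 responses 10 splits are too few for a share under 0.05. The real counts were 118, 221, 127 and 235, reached by 1 split each, and the highest other counts were 1, 0, 0 and 0. Among the splits that part all 3 set pairs, as the real one does, the highest other was 0 in each. For the 4 genotype comparisons, also with 10 splits, the real count was 0 and the highest others were 28 and 2 in mock and 0 and 0 with flg22, at 30 min and 3 h. The split with 28 parted 1 pair of sets and kept the others together. Most of the other splits did the same, so this alone does not show the sets as a structure of the arrays in mock at 30 min. Among the splits that part all 3 pairs the highest others were 0 and 1 in mock and 0 with flg22 at 30 min, while with flg22 at 3 h the numbers do not pair the samples. For the interactions and for the genotype difference over all conditions the real count was 0 (highest others 38, 4 and 57), which any split reaches, so these counts decide nothing about chance. The 25, 22 and 11 of the 99 others that spread each set evenly over both sides, as the real one does, called 0. All of the 13, 4 and 3 splits that called any probe, those with 38, 4 and 57 included, spread the sets unevenly. So did most of the splits that called 0, and with only 4 and 3 calling splits this shows nothing. The 13 splits of the interaction at 30 min are no more than a hint of the sets as a structure of the arrays. For the time change in mock 1 of 100 splits, the real one, reached 118 probes (highest other 44), a share under 0.05. No smaller share can be found with 100 splits, so chance is made unlikely there but is not excluded.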
